A study of Bos taurus with 3 samples.

How the data were processed

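Total RNA was extracted with a column kit from large dense-core vesicles purified from bovine chromaffin cells, and small RNA libraries were prepared with the NEBNext small RNA set from 500 ng of RNA, per the labels' protocols. Both deposited tables cover the same 3 libraries, 2 labelled technical replicates and 1 labelled biological replicate. The labels name no animal, date or batch.

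The deposited count table holds raw read counts (whole numbers) in 919 rows, each a mature miRNA on a precursor hairpin with miRBase identifiers. The genome build UMD3.1 and the package edgeR are named in the submitters' processing notes, and the aligner, the counting tool and the miRBase release are not given in the sources used here. The same table gives values in CPM by the authors, each equal to the count divided by the column total to within the rounding to 2 decimals. The second table holds log2 values by the authors for 459 rows. Tested on the file, these rows are exactly those above 1 CPM in at least 2 libraries, and the values equal log2(CPM + 0.1) with CPM taken over the retained rows. No factor such as TMM entered these values. The log2 table served only as an alternative.

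A mature miRNA with several hairpins has a row for each (73 of 793 mature miRNAs). For 33 of the 50 such miRNAs with at least 100 counts, the rows agreed within 5%, as they would if the same reads were counted at each copy, and for the others they differed by more. Each mature miRNA was represented by its row with the most counts, which counts too few reads where the rows hold different ones. Without this step the column totals are 7330605, 8393478 and 8743314, and abundant miRNAs with several hairpins (miR-103, miR-7, miR-125b, let-7a) can be counted more than once. The sum over rows was an alternative. In 6 pairs, different mature names carried identical counts in all 3 libraries (miR-199a-3p with miR-199c, miR-129 with miR-129-5p, miR-339a with miR-339b and 3 others), so reads were also shared between names, and multi-copy or near-identical miRNAs are uncertain to that extent. Every row named a miRNA.

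CPM were computed from the totals over mature miRNAs. A count of 10 equalled 1.80, 1.60 and 1.49 CPM in technical replicates 1 and 2 and the biological replicate, and a count of 0 allows up to 3 counts. The technical pair was averaged before any mean ± SD over n = 2 preparations. Shares of single libraries carry exact Clopper-Pearson 95% intervals. Correlations used log2(CPM + 1) over miRNAs with at least 10 counts in 1 or more libraries.

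The biological replicate was compared with the technical pair by edgeR 4.0.16 (TMM scaling, quasi-likelihood fit and test, R 4.3.3) on the counts of the 367 miRNAs with at least 10 counts in 1 or more libraries, with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the fold and the F statistic. The fit has 1 residual degree of freedom, and no leave-one-out test was possible because the remaining 2 libraries leave none. Adjusted p-values depend strongly on how edgeR borrows spread between miRNAs: the smallest was 5.3e-32 with the prior degrees of freedom estimated as infinite, and 0.0030 with library totals, where the estimate was 4.30. They are therefore used as a threshold and not as a measure of strength. The same test with each technical library as the lone one was also run, but its spread then comes from a technical library and the biological one (common dispersion of 0.0509 for either, against 0.00316), so it is no measure of technical calls. Data were also simulated for this comparison (367 miRNAs, 10 draws at the fitted spread, 200 miRNAs changed). In these draws 87.8% of 2-fold changes and 76.9% of 1.5-fold changes were recovered, and 2.16% of the calls were false. Draws without change gave 0.2 calls on average. The fitted spread came from the technical pair alone, so the simulation holds no spread between preparations. Its rates apply only under that spread and are not error rates of the calls in the data.

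Before the data were examined, 15 lists of miRNAs were fixed (endocrine and chromaffin, neuronal, DLK1-DIO3 cluster, let-7, miR-30, miR-29, miR-17-92 clusters, and markers of erythrocytes, leukocytes, endothelium, smooth muscle and fibroblasts, striated muscle, hepatocytes, epithelium and hypoxia). miRNAs were matched by name without species prefix, arm and copy number. List medians were placed among 10000 random lists of the same size drawn from the 15 miRNAs nearest in abundance on each side of each member. Members were drawn separately, so the percentiles treat arms of a hairpin and neighbouring hairpins within a list as independent. The rule for the named miRNAs was also fixed then. It took the 20 with the highest mean CPM, the 10 strongest rises and drops among miRNAs with an adjusted p below 0.05 and a mean of at least 100 CPM, and the 4 most abundant members of each list. A few further members are named after their values were seen, as examples within a list. Also fixed were the alternatives on scaling, tool (DESeq2 1.42.0), filters, pseudocount, depth, averaging and left-out libraries, and 3 more were added after seeing the data (miR-375 left out, libraries thinned to equal depth, identical counts kept once). Where miRNA genes neighbour each other was taken from a RefSeq table of assembly ARS-UCD2.0, which matched 325 of 326 hairpins. It is not the authors' build, so no coordinates are given, and miRNA sequences were not used. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1, NumPy 2.4.6 and matplotlib 3.10.9.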

Results

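Small RNA was sequenced from large dense-core vesicles purified from bovine chromaffin cells, to show which miRNAs these vesicles hold. Chromaffin cells are the catecholamine-secreting cells of the adrenal medulla, and large dense-core vesicles are the organelles in which they store catecholamines and peptides before release. The series held 3 libraries, of which 2 were labelled technical replicates and 1 a biological replicate. The labels did not say which step was repeated for the technical pair, nor how many animals stood behind each preparation. The technical pair was therefore averaged and counted as 1 preparation, so that means and standard deviations were taken over n = 2 preparations. No library of whole chromaffin cells or of another fraction was analysed here. The values therefore describe the RNA of the vesicle preparations, and show neither enrichment over the cell nor that a miRNA lay inside the vesicles. After each mature miRNA was counted once, the libraries held 5546771 and 6251664 counts in technical replicates 1 and 2 and 6708654 counts in the biological replicate. The limit set by a count of 0 (3 counts) lay between 0.447 and 0.541 CPM, the usual unit of counts scaled to a common library total. Intervals and limits cover counting error only, since reads were counted without molecular identifiers as far as the labels say.

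The RNA of the vesicle preparations was dominated by miR-375 (MIMAT0009303), a miRNA known for its high level in endocrine cells such as pancreatic beta cells. miR-375 took 39.3% ± 3.31 (SD, n = 2) of all miRNA counts. Its share was 38.1% in technical replicate 1 (exact 95% interval 38.10 to 38.18%), 35.8% in technical replicate 2 (35.77 to 35.85%) and 41.7% in the biological replicate (41.62 to 41.70%). miR-103 held 6.46% ± 0.477, and miR-7, which is also abundant in endocrine and neuroendocrine cells, held 6.06% ± 0.590. Their order differed between libraries, with 6.01% for miR-103 and 7.03% for miR-7 in technical replicate 2 and 6.80% and 5.64% in the biological replicate. Technical replicate 1 had 6.25% and 5.92%, so the order also differed within the technical pair, where miR-7 was further apart than its SD. After miR-103 and miR-7 came miR-21-5p at 4.04% ± 0.665, miR-125b at 3.57% ± 0.166 and miR-101 at 2.64% ± 1.02 (all SD, n = 2). miR-27b, miR-26a, miR-10b, miR-30d, miR-504, miR-379, miR-127, miR-411a, miR-99a-5p, miR-143, let-7i, miR-23a, miR-23b-3p and miR-25 completed the 20 most abundant, with mean shares from 2.47% for miR-27b to 0.901% for miR-25. The 10 leading miRNAs of each library held 70.6% and 69.3% of the counts in technical replicates 1 and 2 and 71.9% in the biological replicate. Of the 20, 15 did not pass the edgeR test between preparations described below. miR-375, with a log2 fold change of 0.35 ± 0.23 (SE), had an adjusted p of 0.23 in edgeR's quasi-likelihood test. In DESeq2 and without a count filter miR-375 passed, with adjusted p-values of 0.0055 and 0.028, and miR-103 did too, with 0.0070 and 0.034. miR-21-5p passed with library totals, with a log2 fold change of -0.34 (edgeR, adjusted p = 0.024).

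**Figure D1:**
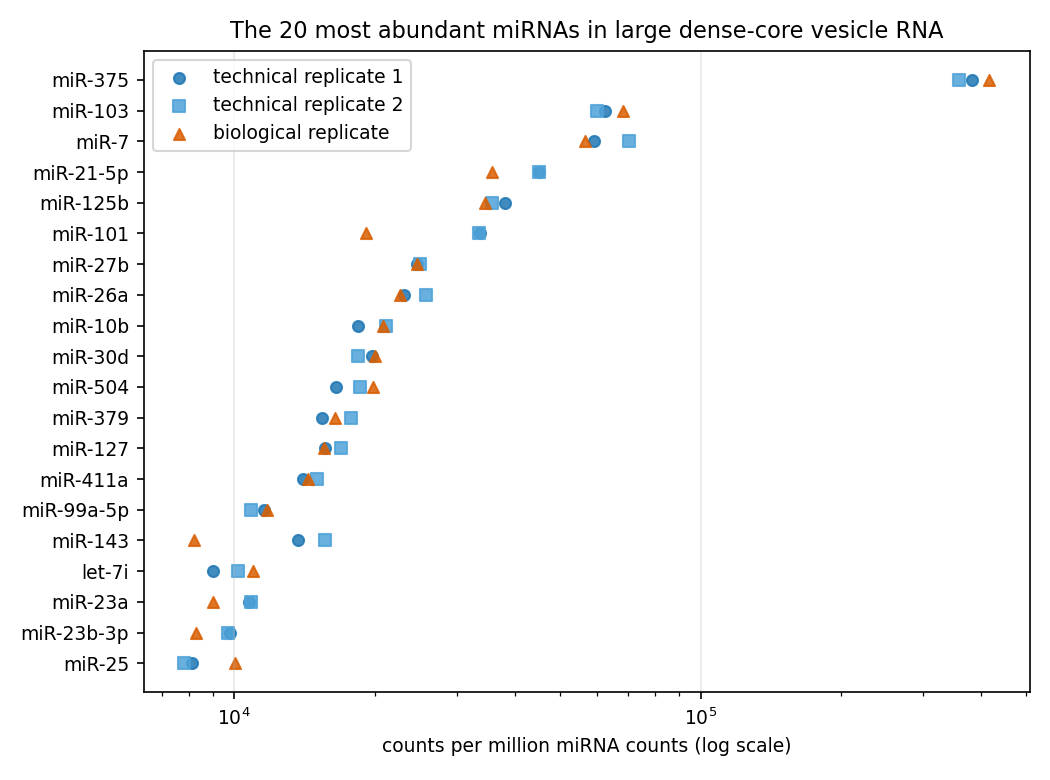
CPM (log axis) of the 20 most abundant miRNAs, with 1 point per library. miR-375 lay between 358079 and 416586 CPM in the 3 libraries, and miR-101 and miR-143 were the members of the 20 with the widest gap between preparations relative to their level.

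At least 10 counts in every library were found for 343 of the 793 annotated mature miRNAs, and 267 had no count in any library. The 56 miRNAs at 1000 CPM or more in every library held 94.7% of the counts on average. No miRNA with at least 10 counts in both technical libraries was at 0 in the biological library, and none was at 0 in both technical libraries with at least 10 counts in the biological one.

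The replicates address how far the vesicle profile repeats, within a preparation and between preparations. Over 367 miRNAs with at least 10 counts in a library, log2(CPM + 1) correlated across miRNAs with Pearson's r = 0.998 and Spearman's rho = 0.997 for the technical pair. For the biological replicate, r was 0.991 against each of the technical replicates. miRNAs are not independent replicates, and these correlations describe 3 libraries. The median absolute log2 ratio was 0.11 between the technical replicates, against 0.29 between the biological replicate and either of them. All 3 pairs differed by more than counting noise. Over the 167 miRNAs with a mean of at least 100 CPM, the chi-square statistic per degree of freedom was 116 for the technical pair, 586 for technical replicate 1 against the biological replicate and 832 for technical replicate 2 against it. No library was thus a second copy of another.

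Between the biological replicate and the technical pair, 139 of 367 miRNAs differed, 65 of them higher and 74 lower in the biological replicate (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p below 0.05). The labels give no treatment, and the comparison sets a library of a second preparation against a technical pair. The largest drops among miRNAs with a mean of at least 100 CPM were those of miR-146b and miR-146a, related miRNAs known from NF-kappaB signalling in immune cells. miR-146b had 2174 and 2461 CPM in technical replicates 1 and 2 and 777 CPM in the biological replicate, a log2 fold change of -1.39 ± 0.10 (SE). miR-146a fell by 1.31 ± 0.13 (SE), to 72.1 CPM from 202 and 204 CPM. Lower by a log2 fold change between -1.15 and -0.96 were miR-450a, miR-450b and miR-424-5p, which are encoded in a common cluster. miR-132, an activity-regulated miRNA of neurons, changed by -1.11 ± 0.10 (SE) to 1118 CPM from 2643 and 2829 CPM. miR-215, miR-126-5p, miR-29c and miR-411b completed the 10 strongest drops, with log2 fold changes from -0.95 to -0.71.

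The largest rise among miRNAs with a mean of at least 100 CPM was that of miR-543, a miRNA of the imprinted DLK1-DIO3 region, at 1031 CPM in the biological replicate against 568 and 587 CPM, a log2 fold change of 1.02 ± 0.09 (SE). miR-9-3p, from a hairpin known for neural expression, rose by 0.89 ± 0.12 (SE). miR-2483-3p, miR-98, miR-7859 and miR-128 rose by 0.77, 0.75, 0.74 and 0.71 on the log2 scale, and miR-95, miR-499, miR-320a and miR-181d by 0.64, 0.63, 0.61 and 0.59. Among the 20 most abundant miRNAs, 3 were higher (miR-504, let-7i and miR-25, by 0.36, 0.38 and 0.52 on the log2 scale) and 2 were lower in the biological replicate. The lower ones were miR-101, at -0.63, and miR-143, at -0.66. miR-504 and let-7i did not pass with library totals or when only miRNAs of at least 100 CPM were fitted, and miR-504 also did not with DESeq2's size factors in edgeR (adjusted p = 0.054). A difference of more than 2-fold was seen for 32 miRNAs, of which 29 passed the test, 6 of them higher and 23 lower. Only 6 of the 32 had a mean of at least 100 CPM, and the others include miRNAs near the floor.

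The spread in this test came from the technical pair alone (1 residual degree of freedom), and the lone biological library was assumed to vary as that pair does, so the p-values compare these libraries and not animals, and the number of calls does not measure how far preparations differ in general. With library totals in place of TMM scaling, 24 miRNAs were higher and 86 lower, and with only the miRNAs of at least 100 CPM fitted, 26 were higher and 44 lower, against 51 and 31 among the same miRNAs in the full fit. TMM placed the biological replicate 0.18 log2 units higher than library totals did, and log2 fold changes are relative to that shift.

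**Figure D2:**
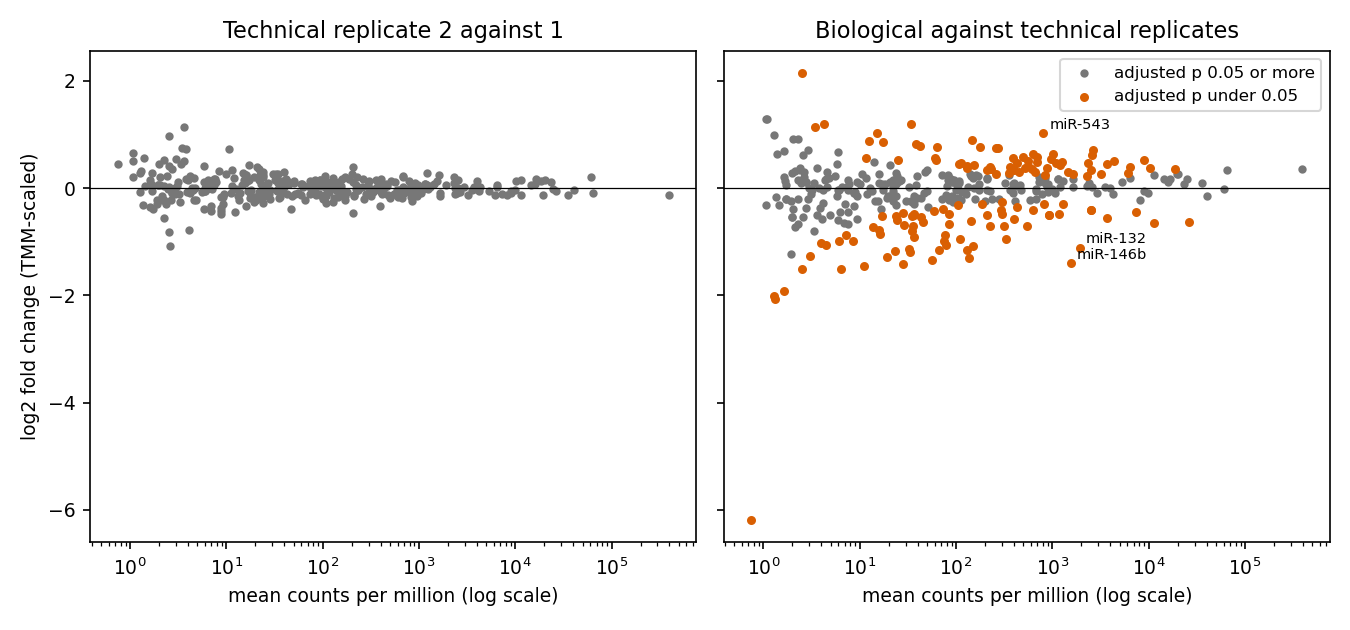
TMM-scaled log2 fold change (vertical axis) against mean CPM (log axis) for 367 miRNAs, as technical replicate 2 against 1 (left) and the biological replicate against the technical pair (right), where orange points had an adjusted p below 0.05. The ratios at left had 1 CPM added to each value, unlike the edgeR folds at right. The spread of scarce miRNAs is therefore not comparable between the panels. The 139 orange points spread to both sides of 0, and the lowest point at right, miR-2313-3p, had 0 counts in the biological replicate and 6 and 12 in the technical ones.

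Among the lists of miRNAs fixed beforehand, the endocrine list held the largest share of counts, most of it miR-375. The endocrine and chromaffin list (miR-375 and miR-7) held 43.4% of the counts on average in the technical pair and 47.3% in the biological replicate, and neither member passed the test. The DLK1-DIO3 imprinted cluster, which is known for its expression in neuroendocrine and brain tissue, held 6.27% ± 0.0628 (SD, n = 2). Its share was 6.04% and 6.59% in technical replicates 1 and 2 and 6.23% in the biological replicate. The technical pair thus differed by more than that SD. Its most abundant members were miR-379, miR-127, miR-411a and miR-409a, and of 53 members tested, 11 were higher, 7 lower and 35 did not pass. miR-543 and miR-3956 rose by 1.02 and 1.19 on the log2 scale, whereas miR-411b fell by 0.71 and miR-376b by 0.99. The neuronal list held 1.13% ± 0.0363, with miR-128, miR-132, miR-218 and miR-129-3p most abundant. Its share was 1.13% and 1.19% in technical replicates 1 and 2, also further apart than the SD. Of its 17 tested members 5 were higher, 4 lower and 8 did not pass. Among the latter, miR-129 and miR-129-5p had identical counts, as had miR-124a and miR-124b, so these are not independent members and their reads count more than once in the share. miR-128, miR-218 and both arms of miR-9 rose (log2 fold changes of 0.71, 0.48, 0.41 for miR-9-5p and 0.89 for miR-9-3p), and miR-132 and miR-212, which come from neighbouring hairpins, fell by 1.11 and 0.62. With library totals the split became 2 higher and 9 lower for the imprinted cluster, and 3 higher and 4 lower for the neuronal list. The medians of the endocrine, imprinted and neuronal lists stood at percentiles 55.9, 49.0 and 35.3 of 10000 random lists matched on abundance. Adjusted over the list alone, the counts were the same for these 3 lists.

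Among the broadly expressed families, the let-7 members that passed the test were higher in the biological replicate, and those of the miR-29 and miR-30 families were lower. let-7 held 3.16% ± 0.231 of the counts, and 6 of its 10 tested members were higher and none lower, among them let-7i, let-7f and let-7a-5p with log2 fold changes of 0.38, 0.38 and 0.45. let-7g, at 0.19, did not pass. The median of let-7, 0.32, stood at percentile 97.3 of the matched random lists, and with library totals 1 member passed. In the miR-30 family (2.52% ± 0.0978), 4 of 7 members were lower and none higher. miR-30a-5p fell by 0.55 and miR-30e-5p by 0.30, while miR-30d, the most abundant at 20072 CPM in the biological replicate, and miR-30c had log2 fold changes of 0.25 and -0.01 and did not pass. In the miR-29 family (0.92% ± 0.20), miR-29c, miR-29b and miR-29d-3p fell by 0.71, 0.41 and 0.88 on the log2 scale. miR-29a (-0.23) and miR-29d-5p (-0.22) did not pass, and 4 of the 5 members were lower when adjusted over the list alone. miR-29a passed in edgeR with library totals (-0.41, adjusted p = 0.021), and both passed when only miRNAs of at least 100 CPM were fitted (-0.38 and -0.36, adjusted p = 0.0022 and 0.036). The medians of miR-30 (-0.30) and miR-29 (-0.41) stood at percentiles 2.41 and 3.25. Members of let-7, miR-29 and miR-30 are known to be closely alike in sequence, so the split of reads within each of these families is uncertain. In the miR-17-92 and related clusters (1.43% ± 0.186), 4 of 14 members were higher and none lower, with miR-25 and miR-92a at 0.52 and 0.46 and miR-20a (0.12) and miR-106b (0.20) not passing. The median of these clusters, 0.014, stood at percentile 43.0, and with library totals 1 was higher and 2 were lower.

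miRNAs known from cells of the vessel wall and connective tissue were present in both preparations, and those that passed the test were lower in the biological replicate. The smooth muscle and fibroblast list held 1.98% and 2.19% of the counts in technical replicates 1 and 2 and 1.22% in the biological replicate. Of its 7 members 6 passed and were lower and none was higher, while miR-145, at -0.24, did not pass. miR-143 fell by 0.66 and miR-199a-3p by 0.42, while miR-199a-5p, miR-199b and miR-214 fell by 1.35, 1.29 and 1.20 on the log2 scale. miR-199c had the same counts as miR-199a-3p in every library, so these are not independent members and their reads count more than once in the share. The median of the list, -0.66, stood at percentile 0.46 of the matched random lists and was -0.84 with library totals. miR-126-3p and miR-126-5p, the endothelial list, fell by 0.49 and 0.71. Together they held 0.182%, 0.189% and 0.113% of the counts in technical replicates 1 and 2 and the biological replicate. Their median stood at percentile 4.28, but they are arms of the same hairpin, whereas the random lists drew members separately. That percentile can therefore overstate how unusual the list is. So can that of the smooth muscle and fibroblast list, with its linked members miR-199a, miR-199c and miR-214. In the leukocyte list (0.0280% in the technical pair and 0.0123% in the biological replicate), miR-146a and miR-142-5p fell by 1.31 and 0.69, while miR-155 and miR-142-3p, at -0.15 and -0.29, and miR-150, at -0.50, did not pass. miR-142-5p did not pass in DESeq2 (log2 fold change of -0.71, adjusted p = 0.099), and the median of the leukocyte list, -0.50, stood at percentile 10.5 of the matched random lists.

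Other lists were scarce. The erythrocyte list held 0.0982% ± 0.0162, nearly all of it miR-486, which rose by 0.53 on the log2 scale. miR-451, the most abundant miRNA of red blood cells, had 131, 126 and 113 counts in technical replicates 1 and 2 and the biological replicate and did not pass, and miR-144 had 0.90, 0.96 and 0.60 CPM. The striated muscle list held 0.0774% ± 0.0154, with miR-499 and miR-1 higher by 0.63 and 0.41 and miR-133a and miR-133b, at 0.11 and -0.32, not passing. miR-1 did not pass with library totals, in DESeq2 or when only miRNAs of at least 100 CPM were fitted. The epithelial list held 0.0029% ± 0.0004, with miR-200c higher by 0.52 and miR-200b (0.30) and miR-141 (-0.20) not passing. miR-200c did not pass with library totals, in DESeq2 or with miR-375 left out, an alternative chosen after seeing the data. miR-200a had 1 count in technical replicate 1 and 3 in the biological replicate. miR-210, a miRNA induced by hypoxia, lay between 76.6 and 85.7 CPM in the 3 libraries and did not pass. The hepatocyte miRNA miR-122 had 6, 6 and 1 counts in technical replicates 1 and 2 and the biological replicate, too few for a test. The medians of the erythrocyte, striated muscle and epithelial lists stood at percentiles 75.3, 85.01 and 84.7. Adjusted over the list alone, the counts of these and the vessel wall, endothelial and leukocyte lists did not change.

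**Figure D3:**
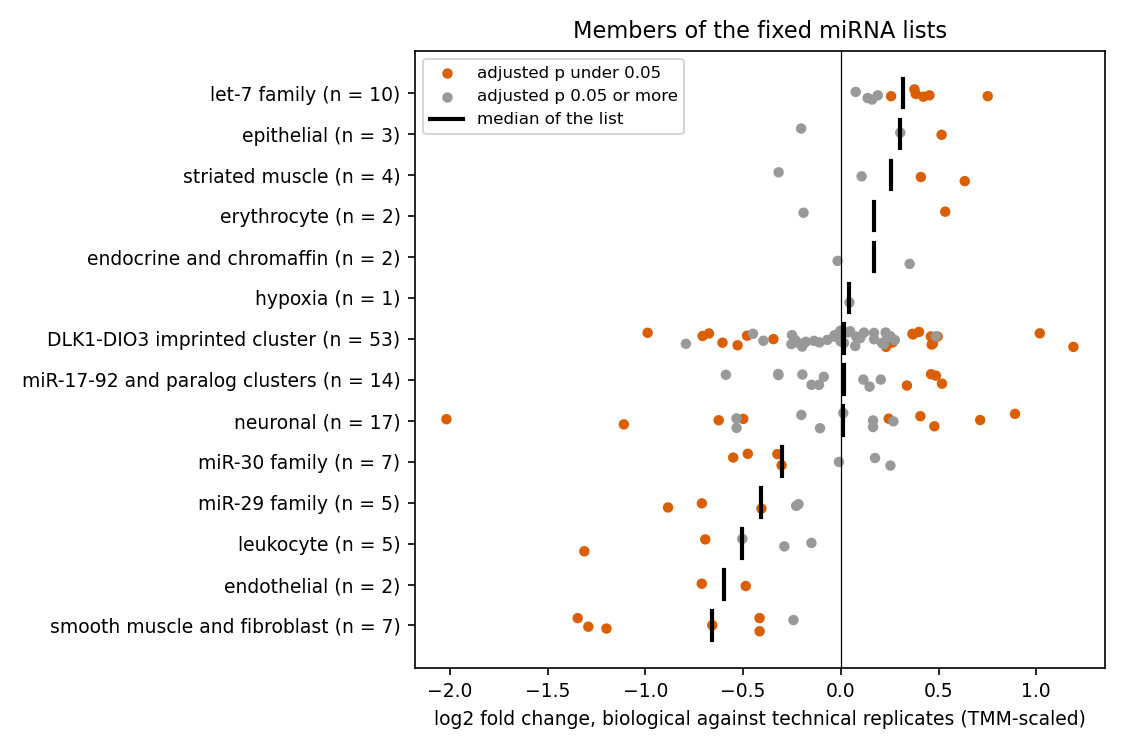
Log2 fold change of the biological replicate against the technical pair (horizontal axis, TMM-scaled) for each tested member of the fixed lists, with orange points at an adjusted p below 0.05 and a black bar at the median of each list. The smooth muscle and fibroblast members lay between -1.35 and -0.24, and the let-7 members between 0.08 and 0.75.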

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

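The tests of calls with miR-375 left out, at equal depth and with identical counts kept once were chosen after seeing the data. At least 17 of the 20 most abundant miRNAs stayed among the 20, while the order of miR-103 and miR-7 did not hold in every library, and the number of calls and their split by direction changed between settings. The share of miR-375 became 29.9% when rows of one miRNA were summed, because miRNAs with several hairpins then add up their rows, and stayed between 37.0% and 39.9% with a library left out. The technical pair's r was 0.999 at 100 CPM or more, 0.997 with a pseudocount of 0.1 CPM and 0.997 in the authors' log2 table. Between preparations r was 0.994 without a filter, 0.984 at 100 CPM or more, 0.988 with the smaller pseudocount and 0.990 in the authors' table. The median absolute log2 ratio of the technical pair was 0.15 without a filter, 0.091 at 100 CPM or more, 0.12 with TMM and 0.11 in the authors' table. Between preparations it was 0.25 without a filter, 0.24 at 100 CPM or more, 0.31 with the smaller pseudocount and 0.29 with TMM. The 139 calls became 86 in DESeq2 (44 higher and 42 lower), where 79 adjusted values were not given, and 70 when only miRNAs of at least 100 CPM were fitted (26 higher and 44 lower), where 167 were tested. With library totals 24 were higher and 86 lower, and with technical replicates 1 and 2 each as the lone library 0 passed in edgeR in either direction (2 and 4 at an unadjusted p below 0.05). The pair that gives the spread then holds the biological library, so these counts say nothing of technical noise. With DESeq2's size factors in edgeR, 118 of the 139 remained, and 97 with library totals. DESeq2's factors moved the folds by a median of -0.0075. Library totals moved them by -0.18, and the 42 calls lost there went from a median absolute log2 fold of 0.38 to 0.20. edgeR's prior degrees of freedom, infinite with TMM, were 5.04 and 4.30, which also enters the count. Calls numbered 120 with miR-375 left out, 137 at equal depth and 132 with identical counts kept once. More than 2-fold differences numbered 114 without a filter and 7 at 100 CPM or more, and 32 to 37 with a technical library left out. The endocrine list held 6.06% without miR-375 and 9.97% of the counts left when miR-375 was removed from each library. The smooth muscle and fibroblast list held 0.51% without miR-143 and 2.70% with miR-375 removed. With a library left out, these lists ranged from 43.4% to 45.7% and from 1.60% to 2.08%. The median log2 fold of the endocrine list was -0.013 with library totals and 0.020 at 100 CPM or more. That of the smooth muscle and fibroblast list was -0.84 with library totals, and from -0.73 to -0.58 with a technical library left out. Where no construction is named, the cause was not tested. Of 71 named miRNAs none that passed the test changed direction under these alternatives. With library totals 8 lost and 2 gained their call, and the DLK1-DIO3 member miR-409a lost its call in 7 alternative tests and kept it at equal depth and with a prior count of 0.1. List medians at 100 CPM or more could not be given where no member reached that level. No paired analysis was possible because the groups share only 1 replicate number and the biological group has 1 library.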

Other observations

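The test with miR-375 left out, the test at equal depth and the test on neighbouring hairpins were set out before their own results were seen. The first 2 of these were nevertheless chosen after the data had been examined. The other tests here were chosen after their results. Beyond the fixed lists, 4 of the 5 tested miRNAs of the miR-424, miR-450, miR-542 and miR-503 cluster were lower in the biological replicate. These were miR-424-5p, miR-450a, miR-450b and miR-503-5p, with log2 fold changes of -0.96, -1.15, -1.08 and -1.51, and miR-424-3p, at -0.34, did not pass. The cluster held 0.058% and 0.056% of the counts in technical replicates 1 and 2 and 0.024% in the biological replicate. miR-195 and miR-497, which neighbour each other, fell by 0.62 and 0.52 on the log2 scale, and both arms of miR-1388 fell by 1.00 (5p) and 1.16 (3p). The large ruminant families miR-2284 and miR-2285, with 63 annotated members, held 0.068% ± 0.0050 (SD, n = 2) of the counts, and of 30 tested members 2 were higher and 3 lower. All these were picked after their values were seen.

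The difference between preparations was not evenly spread over the genome. Among 130 tested hairpins in 35 groups of neighbours, each at most 10 kb apart, the group accounted for 54.9% of the variance of log2 fold changes, against a median of 25.9% when folds were shuffled (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give). Without the largest group the share was 76.0% against 37.0% (permutation p = 1e-04). That group, 41 hairpins of the DLK1-DIO3 region, did not move as a whole, with miR-543 at 1.02 and miR-411b at -0.71. With each family number kept once per group the share was 56.1% against 25.9% (permutation p = 3e-04). In the technical pair the same groups accounted for 32.8% against 26.0% (permutation p = 0.14). The technical ratios had 1 CPM added to each value, unlike the edgeR folds, so this share is not a like-for-like reference. The share above that of shuffled folds between preparations argues against noise or bias specific to each mature miRNA as the whole source. Differences in the transcription or cell source of miRNA clusters remain a hypothesis, found and tested on the same data. The largest group did not follow it as a whole. The arms of single hairpins leave noise or bias specific to each mature miRNA open. Over 34 pairs the 5p and 3p folds correlated with r = 0.60 (across miRNAs, permutation p = 0.0013, Spearman's rho = 0.38, permutation p = 0.014). Without the pairs of miR-2313 and miR-199a r was 0.29 (permutation p = 0.054). Between the technical replicates r was 0.44, again on ratios with 1 CPM added. Over the 20 pairs at 10 CPM or more r between preparations was 0.34 (permutation p = 0.069). Of 7 pairs with both arms past the test, 5 moved in the same direction. The arms of miR-193a and of miR-2483 passed in opposite directions. GC content was not tested, since sequences were not used.

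The 139 calls between the biological replicate and the technical pair were weighed against technical sources. With every library thinned to the smallest total, 95.7% of the 139 calls remained, so most calls did not need the difference in depth. The totals lay close, from 5546771 to 6708654 counts, and the fit already allows for them. Thinning therefore had little room to lose calls and is weak as a test of depth. With miR-375 removed, 86.3% remained (52 higher and 68 lower). That lies between the 50% and 90% set as marks for and against the share of miR-375, before this result but after the data were examined. The TMM-scaled folds moved by a median of only -0.019, from -0.020 to -0.0064 over 366 miRNAs. The 19 lost calls had a median absolute log2 fold of 0.324 before and 0.317 after. edgeR's prior degrees of freedom went from infinite to 5.62, so the lost calls are no evidence for that share. TMM trims miRNAs at the extremes of abundance, so the scaling itself left the folds little room to move when miR-375 was removed. That they stayed therefore does not decide whether its share is a source, and the calls kept missed the 90% mark. Library totals with miR-375 left out were not tested. The second preparation has 1 library, so a difference in library batch cannot be told apart from a difference between animals or vesicle preparations.

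Carry-over of RNA from cells of the vessel wall or from blood is a candidate source of the lower members of the smooth muscle and fibroblast, endothelial and leukocyte lists, although of the leukocyte list 2 of 5 passed. Of the 14 tested members 10 passed and were lower (71.4%), under the 80% taken as the mark, and none was above 0. miR-199c, with the same counts as miR-199a-3p, is included in both numbers, and arms of a shared hairpin are counted separately. The neighbour of miR-143, miR-145, is also known as abundant in smooth muscle. It had 14, 12 and 11 counts in technical replicates 1 and 2 and the biological replicate, against 76060, 97879 and 55048 of miR-143. The log2 fold change of miR-145 was -0.24 and did not pass. Why miR-145 was so low, and what that level means for smooth muscle as the source of miR-143, was not tested. The fold of a single miRNA this near the floor does not weigh for or against that source. A uniform difference in all other cell types stays open as well. The erythrocyte and striated muscle members had a median log2 fold of 0.26, and 3 of the 6, miR-486, miR-499 and miR-1, passed and were higher, which goes against it. However, miR-451, the marker most specific to red blood cells, was at -0.19 ± 0.20 (SE), not apart from the -0.58 median of the 3 lists by 2 SE, the call of miR-1 was lost with library totals and in DESeq2, and miR-486 and miR-499 may also be made by the chromaffin cells, which was not tested. The vesicles were purified, but no fraction against which carry-over could be measured was analysed here. The same limit holds for RNA from the rest of the chromaffin cell.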
